A study of Homo sapiens with 8 samples.

How the data were processed

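Poly-A RNA of MDA-MB-231 cells, an established human triple-negative breast cancer line, was sequenced as strand-specific libraries. The 8 libraries form 6 groups: vehicle, 1-SO and 1-S, each with and without UV-A. Per the labels, the vehicle libraries come from an earlier series and were analysed again, and the study was run in 2 rounds. Round 1 (passage 8) holds vehicle and 1-SO, and round 2 (passage 32 to 34) holds vehicle and 1-S, each with 1 irradiated and 1 shielded library. Per the labels, cells were seeded at 600000 per well in 1.8 mL and treated with 10 µM compound or 1% DMSO, with a 24 h exposure. Irradiation lasted 30 min under 8 bulbs (325 to 375 nm), with 1 plate irradiated and 1 plate covered. Vehicle therefore has 2 libraries per irradiation state, 1 per round, and each compound has 1.

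Raw read counts per gene, without normalization, are the counts of the deposited count tables. The deposited FPKM tables hold each count divided by the listed gene length and the library total: 100% of nonzero values lay within 0.1% of that quotient. The authors' 9 comparison tables hold a log2 fold change for 1 library against another. The same deposited tables hold a p-value and an adjusted p-value for each gene. Which tool made these tables is not stated. The submitters' processing notes name TopHat, DESeq2, STAR-Fusion, STAR 2.5, HTSeq 0.6.1 and edgeR 3.16.5, and the builds hg19 and hg38, with no role or order. Of the gene identifiers found in the GENCODE 29 annotation of hg38, 0.576% had identical coordinates in the table of round 1 and 95.2% in that of round 2. The 2 rounds therefore list different gene models, and positions below are those of hg38. That the reads were counted on these models is inferred from the listed coordinates.

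The 2 count tables list 48162 and 58676 genes, of which 45341 are in both, matched by Ensembl identifier. Only these were analysed. Genes listed in 1 round took 0.766% to 1.33% of the counts of the compound libraries. No such gene was over 2-fold above both vehicle libraries of its round with 100 counts or more. Total counts were 18.8 M (vehicle, shielded), 15.8 M (vehicle, irradiated), 21.6 M (1-SO, shielded) and 16.0 M (1-SO, irradiated) in round 1. In round 2 they were 22.6 M and 21.8 M (vehicle, shielded and irradiated) and 21.7 M and 22.0 M (1-S, shielded and irradiated). A count of 3, the upper limit that a count of 0 allows, corresponds to between 0.133 and 0.19 counts per M (CPM) in these libraries. This limit covers counting error only, since the reads carry no molecular identifiers.

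Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15891 genes (13252 protein-coding), and libraries were scaled by TMM. Before the data were examined, the comparisons, tests, gene lists, rule for named genes and alternative settings were fixed. The planned design has a term for round and 6 conditions (7 coefficients, 1 residual degree of freedom, median prior degrees of freedom 26.8, common biological coefficient of variation 12.4%). Every contrast was tested with the edgeR quasi-likelihood test and adjusted by Benjamini and Hochberg over the tested genes at 0.05. The compound libraries stand alone in their groups and are assumed to vary like the vehicle pairs. The only residual degree of freedom is the difference between rounds in the response of vehicle to UV-A, so that difference sets the spread and also enters the fitted compound contrasts. For this reason fitted values of 1-SO or 1-S against vehicle are mostly given beside the ratio of the libraries within a round (TMM CPM, prior count 2), which has no replicate and no test. Whether round pairs the libraries was checked by the correlation across genes of the deviations of round 1 from the group means, shielded against irradiated vehicle, which was 0.779.

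A second design was chosen after the data were seen. It has a term for round, a UV-A effect in each round, an effect of 1-SO and an effect of 1-S (6 coefficients, 2 residual degrees of freedom, median prior degrees of freedom 30.1). Its UV-A effect in a round averages the vehicle pair and the compound pair (2 irradiated against 2 shielded libraries), and its spread comes from how far the pairs differ. With 1 irradiated and 1 covered plate, that spread holds no variation between plates or between exposures. Intervals of differences between compounds are 95% intervals of the same models.

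The 30 gene lists held immediate early genes, targets of NRF2, AhR, ATF4, p53, LXR, NF-kB and hypoxia, heat shock genes, endoplasmic reticulum chaperones, DNA repair genes, cholesterol biosynthesis, fatty acid synthesis, fatty acid oxidation with PPAR targets, interferon response genes, mitotic genes, DNA replication genes, metallothioneins with zinc transport, YAP and TGF-beta targets, lysosome and autophagy genes, glycolysis, nuclear respiratory chain subunits, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, nuclear retained RNAs, mesenchymal and luminal markers, and markers of blood and stromal cells. Lists were tested with camera (limma 3.58.1, log2 CPM with prior count 2, preset correlation 0.01) and adjusted over the 30 lists. The test was repeated with an estimated correlation and with fry, and list medians were placed among 10000 random lists matched on expression. The estimated correlation rests on the 1 or 2 residual degrees of freedom of the designs. That test could therefore hardly pass, and its adjusted p does not decide for or against a list. Similarity of responses was computed as a correlation across genes between within-round ratios that share no library. Genes are not independent replicates, so it carries no p-value.

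Named genes were the 8 higher and 8 lower protein-coding genes with the largest fitted change among those past the threshold, with a mean log2 CPM of at least 2. For UV-A in vehicle they also had to have the same sign in both rounds. Where fewer passed, the largest changes that did not pass filled up to 4 per direction and are given as values. For interactions and for 1-SO against 1-S the numbers were 5 and 2. Up to 8 list members with a mean log2 CPM of at least 1 were added, and a fixed set of 14 stress genes could be named everywhere. Examples of a list are among its largest changes.

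Alternatives fixed before the data were examined were RLE scaling, no low-count filter, limma-trend, the DESeq2 1.42.0 Wald test, no term for round, an additive design, within-round ratios, leaving out each vehicle library, an estimated correlation, fry, a filter at a mean log2 CPM of 4, and FPKM. Leaving out a vehicle library removes the residual degree of freedom of the planned design, so it was tested in the additive design (round, UV-A and compound). That design has 1 UV-A effect and 1 effect per compound. It therefore cannot test a compound effect that depends on UV-A. Chosen after the data were seen were the second design with each irradiated library of round 1 left out, a filter at a mean of 20 counts per library in each round, and an offset for transcript GC content and length. The tests of genomic span (300 kb or more against under 100 kb) and of overlapping gene models (50% of exonic bases) also date from after the data were seen, and for the overlap the prediction was written before any overlap was computed. The comparisons were tested on simulated data in which 200 of the 15891 genes were changed. Changed genes had a mean CPM of at least 4, and the other genes had no UV-A response. All libraries were drawn with the fitted spread, and a change in vehicle was the same in both rounds. The recovery below holds for such data and is not the power of these tests on the real libraries. At 2-fold, 91.5% were recovered for UV-A in vehicle, 73% for 1-SO with UV-A, 70% for 1-S with UV-A and 91% for UV-A in round 1, and at 4-fold 99% or more in each. Further deposited tables that repeat these values, or hold a subset chosen by the authors, were left out.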

Results

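RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, exposed to vehicle (1% DMSO) or to 10 µM of 1 of 2 compounds, with or without 30 min of UV-A. The compounds are the sulfide 1-S, which is 2,8-diacetoxymethyldibenzothiophene, and its S-oxide, called 1-SO. Round 1 held vehicle and 1-SO and round 2 held vehicle and 1-S, so vehicle had 2 libraries per irradiation state and each compound group had 1 (n = 1, no replicate). Total counts ranged from 15.8 M to 22.6 M per library, and 15891 genes were tested. Values are log2 fold changes with the standard error (SE) of the edgeR model unless a ratio within a round is named, and adjusted p-values are from the edgeR quasi-likelihood test. The labels do not give the time from irradiation to RNA extraction, or whether compound was still in the medium during irradiation. Each round had 1 irradiated and 1 shielded plate, so UV-A cannot be told apart from the plate, and compound cannot be told apart from round when 1-SO is set against 1-S.

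The first question was what UV-A did to the cells, in vehicle and on average over the pairs of a round. In round 1, irradiated cells held far more mRNA for MMP1, a secreted collagenase, and for CYP1A1 and CYP1B1, cytochrome P450 enzymes induced through the aryl hydrocarbon receptor (AhR). MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160 in hg38) rose by 2.995 ± 0.131, CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) by 2.42 ± 0.173 and CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) by 2.14 ± 0.0956. The adjusted p was 8.89e-17 for MMP1 and CYP1B1 and 2.97e-12 for CYP1A1. ARC, an activity-induced cytoskeletal gene, rose by 1.91 ± 0.169, and CDKN1C, an inhibitor of cyclin-dependent kinases, by 1.67 ± 0.187. The immediate early transcription factor genes FOS (1.53 ± 0.17), FOSB (1.499 ± 0.213) and EGR1 (1.22 ± 0.105) rose as well. These values average the vehicle pair and the 1-SO pair of round 1 (2 irradiated against 2 shielded libraries). Their p-values measure how far pairs of the same round differ. Variation between plates or between exposures is not in them. In the vehicle pair alone the ratios were 2.44 for MMP1, 2.12 for CYP1A1, 2.05 for CYP1B1, 1.24 for ARC, 1.26 for CDKN1C, 1.33 for FOS, 1.43 for FOSB and 1.19 for EGR1.

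The protein-coding transcripts (mean log2 CPM of at least 2) that fell most with UV-A in round 1 include several from very long genes. GPC6, which encodes a cell-surface glypican (chromosome 13, span 1180.6 kb), fell by 3.64 ± 0.26 (adjusted p = 6.69e-14) and FHIT, a gene across a fragile site (chromosome 3, span 1502.2 kb), fell by 3.20 ± 0.35. PRKG1, a cyclic GMP-dependent kinase, changed by −2.73 ± 0.315, NEGR1, a neural adhesion molecule (chromosome 1, span 886.8 kb), by −2.66 ± 0.187 and COL6A3, a collagen VI chain, by −2.38 ± 0.189. ANK2 (−2.33 ± 0.158), PARD3B (−2.26 ± 0.2) and RAD51B, a recombination repair gene (−2.20 ± 0.278), followed. In the vehicle pair alone the ratios were −3.59 for GPC6, −2.64 for FHIT, −2.60 for PRKG1, −1.97 for NEGR1, −1.90 for COL6A3, −1.89 for ANK2, −1.64 for PARD3B and −1.87 for RAD51B. Among the fixed stress genes, HMOX1, the heme oxygenase (0.54 ± 0.153, adjusted p = 0.0135), ATF3 (0.66 ± 0.167, adjusted p = 0.0059) and the chemokine gene CXCL8 (0.52 ± 0.151, adjusted p = 0.0162) rose on average. The ratio of ATF3 was 0.24 in the vehicle pair and 1.05 in the 1-SO pair, that of CXCL8 0.24 and 0.77, and that of HMOX1 0.38 and 0.68. CDKN1A (0.22), HSPA1A (0.32), HSPA1B (0.20), DDIT3 (0.22), HMGCS1 (0.18) and IL6 (−0.64) did not pass.

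In all, 2390 of the 15891 genes passed in round 1, 855 higher and 1535 lower. This design, with a UV-A effect per round, was chosen after the data were seen. DESeq2 called 1329 genes. Leaving out the irradiated vehicle or the irradiated 1-SO library cannot test the count of 2390. Round 1 then holds 1 irradiated library, and the spread comes from the pairs of the other round alone.

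**Figure D1:**
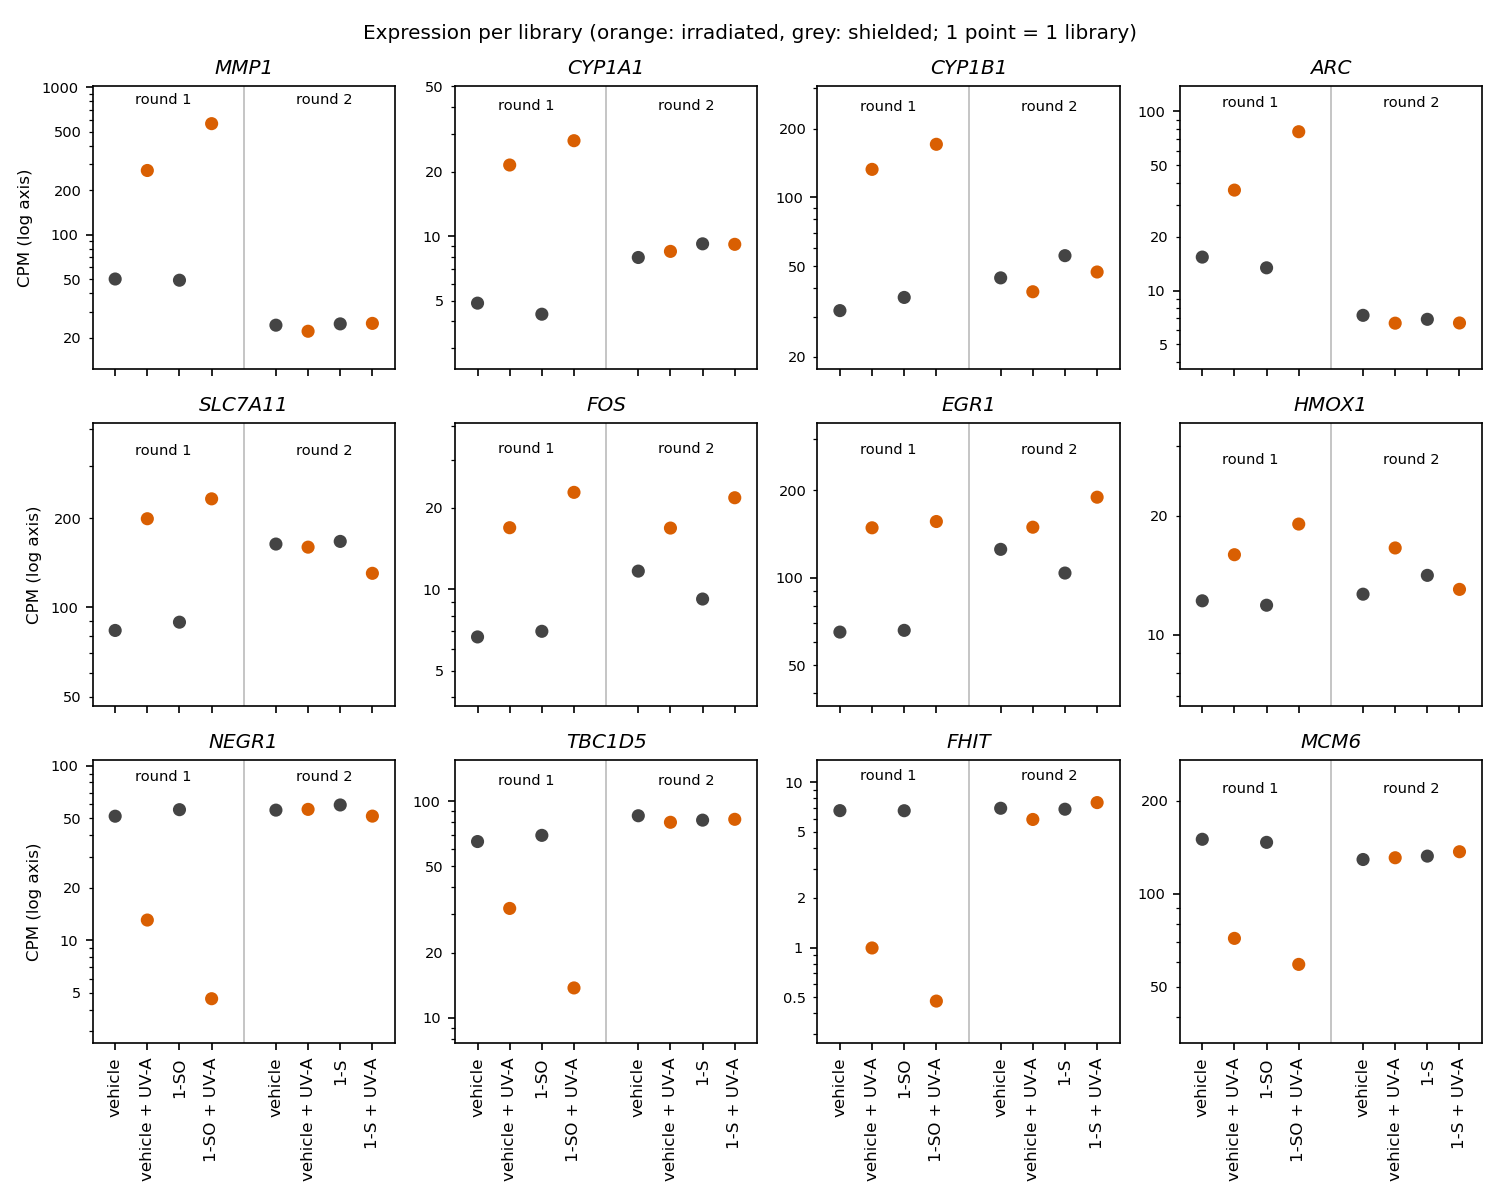
Expression of 12 genes in the 8 libraries, as CPM on a log axis, with 1 point per library, by round, compound and irradiation. In round 1 MMP1 went from 50.0 to 272.2 in vehicle and from 49.1 to 565.6 with 1-SO, while the 4 libraries of round 2 lay between 22.12 and 25.01. NEGR1 went from 51.3 to 13.0 in vehicle and from 55.9 to 4.62 with 1-SO in round 1.

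By fixed gene lists, the DNA replication genes fell nearly as a block with UV-A in round 1: 38 of 41 measured members fell and 0 rose (41 fell when adjusted over the list alone). They include E2F2, a cell cycle transcription factor (−1.35 ± 0.154), MCM6, a helicase subunit (−1.19 ± 0.0916), GINS2 (−1.09) and UNG (−1.06). The camera adjusted p was 4.75e-23, and adjusted p = 0.59 with an estimated correlation. Of 78 cytosolic ribosomal protein genes 69 fell and 0 rose (73 adjusted over the list alone, median −0.39), as in RPS29 (−0.65), RPS21 (−0.58) and RPL35 (−0.58). Their adjusted p was 1.72e-19, and adjusted p = 0.765 with an estimated correlation. Among glycolysis genes 14 of 19 fell (16 adjusted over the list alone, adjusted p = 2.44e-07, and adjusted p = 0.59 with an estimated correlation), among them LDHA (−0.87) and ENO1 (−0.65). Of 59 nuclear respiratory chain subunits 16 fell (23 adjusted over the list alone, adjusted p = 1.08e-06, and adjusted p = 0.765 with an estimated correlation), with COX8A at −0.60 and UQCRQ at −0.53.

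NRF2 targets, which encode antioxidant and iron-storage proteins, rose: 18 of 30 measured members were higher and 0 lower (20 adjusted over the list alone). AKR1C1, an aldo-keto reductase, rose by 1.38 ± 0.212, SLC7A11, the cystine transporter, by 1.32 ± 0.0918, NQO1, a quinone reductase, by 1.25 ± 0.0847 and FTL, the ferritin light chain, by 1.10 ± 0.0866. The list's adjusted p was 2e-10, and adjusted p = 0.59 with an estimated correlation. Of 8 AhR targets 6 rose (7 adjusted over the list alone, median 1.12, adjusted p = 1.14e-07, and adjusted p = 0.59 with an estimated correlation), including SERPINB2 at 2.33 ± 0.35. Mitotic genes were higher for 12 of 34 members and lower for 1 (12 and 1 adjusted over the list alone), as in KIF20A, a mitotic kinesin (0.78), NEK2 (0.73) and CDC25C (0.69). Their adjusted p was 0.00153, and adjusted p = 0.765 with an estimated correlation. In the vehicle pair of round 1 the mitotic median was 0.34 and in the 1-SO pair 0.00639. Lysosome and autophagy genes rose for 8 of 27 (9 adjusted over the list alone, adjusted p = 0.0432, and adjusted p = 0.765 with an estimated correlation), led by SQSTM1, a selective autophagy receptor (0.88). Replication-dependent histones rose for 6 of 14 (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.0427, and adjusted p = 0.765 with an estimated correlation), with HIST1H2BD at 0.77.

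4 more lists passed camera as lower in the same comparison. Of 20 YAP and TGF-beta targets 9 fell (10 adjusted over the list alone, adjusted p = 0.000264, and adjusted p = 0.765 with an estimated correlation), among them the collagen IV gene COL4A1 (−1.15). Mesenchymal markers fell for 8 of 14 and rose for 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00867, and adjusted p = 0.765 with an estimated correlation). PLAU, the urokinase, was at −1.20 ± 0.089 and the intermediate filament gene VIM at −0.37, whereas CD44 rose (0.33). Hypoxia targets fell for 7 of 25 and rose for 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00539, and adjusted p = 0.765 with an estimated correlation), with BHLHE40 at −0.86 and ADM at 0.56. Fatty acid synthesis genes fell for 6 of 14 (6 adjusted over the list alone, adjusted p = 0.0176, and adjusted p = 0.765 with an estimated correlation), with the desaturase gene SCD at −0.66.

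The other lists did not pass camera in round 1. Immediate early genes rose for 7 of 37 and fell for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.158), with JUN at −0.47. Heat shock genes rose for 2 of 21 and fell for 4 (3 and 5 adjusted over the list alone). HSPA6, a strictly inducible chaperone, rose by 2.31 ± 0.372 (ratio 1.46 in vehicle and 2.77 in 1-SO) and HSPD1 was at −0.56, and the list's median (−0.0959) and mean (0.000867) differ in sign. DNA repair genes rose for 2 of 40 and fell for 10 (3 and 12 adjusted over the list alone), with the mismatch repair gene MSH6 at −0.64. Interferon response genes rose for 6 of 35 and fell for 4 (7 and 4 adjusted over the list alone), NF-kB targets rose for 4 of 26 and fell for 5 (4 and 5 alone), with CSF2 at −1.43 ± 0.275, and ATF4 targets rose for 5 of 29 and fell for 3 (5 and 4 alone). Of p53 targets 3 of 26 rose and 1 fell (3 and 1 adjusted over the list alone, median −0.0185, mean −0.00961, camera direction up, adjusted p = 0.855). Cholesterol biosynthesis genes rose for 1 of 25 and fell for 4 (2 and 4 adjusted over the list alone), fatty acid oxidation and PPAR targets rose for 1 of 17 and fell for 2 (1 and 2 alone), with ANGPTL4 at −1.04, and LXR targets fell for 2 of 8 (1 higher and 2 lower alone). Endoplasmic reticulum chaperones fell for 2 of 20 (2 adjusted over the list alone), metallothioneins for 2 of 7 (3 alone) and mitochondrially encoded mRNAs for 1 of 13 (0 alone). Nuclear retained RNAs rose for 2 of 8 (2 adjusted over the list alone), MALAT1 (0.86 ± 0.166, ratio 1.64 in vehicle and 0.08 in 1-SO) and NEAT1 (0.38). Luminal markers rose for 1 of 15 and fell for 3 (1 and 3 adjusted over the list alone), 0 of 3 blood cell markers passed, and of 3 stromal markers COL1A1 rose (0.52).

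In round 2 UV-A was followed by much smaller changes. FOS rose by 0.88 ± 0.157 (adjusted p = 0.00941), EGR1 by 0.56 ± 0.102 (adjusted p = 0.0109) and EIF4A1, a translation initiation helicase gene, by 1.14 ± 0.203. The ratio of FOS was 0.52 in the vehicle pair and 1.23 in the 1-S pair, that of EGR1 0.25 and 0.87, and that of EIF4A1 1.29 and 0.94. The mitochondrial transcripts MT-ND3 (0.50 ± 0.0932) and MT-ND4L (0.44 ± 0.0895) rose, and NEAT1, a nuclear noncoding RNA, fell by 0.62 ± 0.0869 (adjusted p = 0.000788). MMP1 (−0.06), CYP1A1 (0.04) and CYP1B1 (−0.22) did not pass. In all 12 genes passed with edgeR, 9 higher and 3 lower, while limma-trend called 3 (0 higher, 3 lower), DESeq2 3 (1 higher, MT-ND3, and 2 lower) and the GC and length offset 2 (0 higher, 2 lower). The higher calls, FOS, EGR1 and EIF4A1 among them, are thus lost with limma-trend and with the offset, whereas NEAT1 stayed lower in each of these 3 settings. Among the 9, named after their values were seen, are JCHAIN and IGLC2, immunoglobulin transcripts of plasma cells, at 0 CPM in round 1 and, in round 2, seen almost only in the irradiated libraries. The UV-A ratios in 1-S and in vehicle of round 2 had a correlation across genes of 0.0339 over 15891 genes (0.0726 at a mean log2 CPM of at least 4), so the averaged pairs share little. The count was 43 without the irradiated vehicle library of round 1 and 51 without the irradiated 1-SO library, both of the other round, which enter through the shared spread. Ribosomal protein genes were above 0 for 78 of 78 members (1 rose, 14 adjusted over the list alone, median 0.16, adjusted p = 7.88e-16, and adjusted p = 0.836 with an estimated correlation). Immediate early genes rose for 2 of 37 (11 adjusted over the list alone, adjusted p = 5.54e-05, and adjusted p = 0.836 with an estimated correlation). These are 2 of the 10 lists that passed camera in round 2, all of them higher. No camera call in any comparison held with an estimated correlation, a test that could hardly pass with 1 or 2 residual degrees of freedom.

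The UV-A effect differed between rounds for 1594 genes, 514 more positive and 1080 more negative in round 1 (801 by DESeq2). The difference was 3.06 ± 0.198 for MMP1 (adjusted p = 2.65e-12), 2.38 ± 0.239 for CYP1A1, 2.36 ± 0.136 for CYP1B1 and 1.51 ± 0.129 for SLC7A11. It was −3.56 ± 0.294 for GPC6, −3.16 ± 0.403 for FHIT and −2.72 ± 0.363 for PRKG1. EGR1 also differed (0.66, adjusted p = 0.00289), whereas FOS (0.65, adjusted p = 0.0712) and HMOX1 (0.40, adjusted p = 0.257) did not pass. By list, 35 of 41 replication genes (38 adjusted over the list alone) and 72 of 78 ribosomal protein genes (76 alone) were more negative in round 1, and 13 of 30 NRF2 targets (16 alone) and 6 of 8 AhR targets (7 alone) more positive. The adjusted p with an estimated correlation was between 0.549 and 0.712 for these lists. Across 15891 genes the ratios of the vehicle pairs of the 2 rounds had a Pearson correlation of −0.041. The rounds differ in passage and list different gene models. The p-values of the difference between rounds hold no variation between plates or between exposures.

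The planned test of UV-A in vehicle, averaged over both rounds (2 against 2 libraries), called 0 of 15891 genes with edgeR, and 0 with limma-trend and DESeq2. 468 genes had an unadjusted p under 0.05, less than the 5% of tested genes expected if nothing changed. The further counts at this level given below also lie under that 5%. They are thus no sign of changes just short of the threshold. The test was conservative there, and 0 calls do not show that nothing changed. Among protein-coding genes with a mean log2 CPM of at least 2 the largest averages with the same sign in both rounds were 1.10 ± 0.288 for CYP1A1 (adjusted p = 0.719), 0.94 for EIF4A1, 0.91 ± 0.217 for FOS (adjusted p = 0.532) and 0.79 for PIF1, and −1.38 for GPC6, −1.20 for FHIT, −1.15 for CST2 and −1.14 for COL6A3 (adjusted p = 0.248). For CYP1A1 the vehicle ratio was 2.12 in round 1 and 0.09 in round 2, and for GPC6 −3.59 and −0.06. Mitotic genes had a median of 0.256 (0 passed, 9 adjusted over the list alone, adjusted p = 8.12e-09, and adjusted p = 0.979 with an estimated correlation) and histones 0.487 (0 passed, 0 alone, adjusted p = 2.51e-06, and adjusted p = 0.979 with an estimated correlation). The count became 8 without the shielded or without the irradiated vehicle library of round 2, 22 without a low-count filter and 25 with an offset for GC content and length. In the authors' comparison tables, each for 1 pair of libraries, 8 genes passed in vehicle of round 1 (3 higher, among them MMP1, CYP1A1 and CYP1B1, and 5 lower, among them GPC6, FHIT and NEGR1) and 0 in round 2.

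What UV-A did in cells exposed to 1-SO was asked by comparing the irradiated with the shielded 1-SO library. MMP1 rose by 3.53 ± 0.385 (adjusted p = 2.23e-05), CYP1A1 by 2.69 ± 0.414, ARC by 2.52 ± 0.306 and CYP1B1 by 2.23 ± 0.357. CDKN1C (2.05), RRAD, a Ras-related GTPase gene (1.90), FOS (1.70 ± 0.308), SLC7A11 (1.38 ± 0.262), HSPA6 (2.90 ± 0.637) and EGR1 (1.25 ± 0.233) rose too. FHIT (−3.81 ± 0.779), NEGR1 (−3.59 ± 0.399, adjusted p = 9.56e-06), GPC6 (−3.59 ± 0.735), PARD3B (−3.11), COL6A3 (−2.96) and ANK2 (−2.87) fell. The growth factor gene CSF2 (−1.78), E2F2 (−1.47) and PLAU (−1.35) fell as well. HMOX1 (0.68, adjusted p = 0.416), ATF3 (1.05, adjusted p = 0.101), CXCL8 (0.78), CDKN1A (0.45) and HSPA1A (0.49) did not pass.

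In 1-SO 166 genes passed with UV-A, 22 higher and 144 lower. Of the 139 lower protein-coding calls with a mean log2 CPM of at least 2, 72 span 300 kb or more (51.8%, against 3.42% of the 10569 tested), and of 20 higher calls 0 do. By list, 10 of 41 replication genes fell (29 adjusted over the list alone, adjusted p = 6.51e-11, and adjusted p = 0.884 with an estimated correlation), as in CCNE2 (−1.33) and MCM6 (−1.31). NRF2 targets rose for 5 of 30 (11 adjusted over the list alone, adjusted p = 1.43e-07, and adjusted p = 0.884 with an estimated correlation) and AhR targets for 4 of 8 (6 alone, adjusted p = 0.00229, and adjusted p = 0.884 with an estimated correlation). YAP and TGF-beta targets fell for 4 of 20 (6 adjusted over the list alone, adjusted p = 0.000543, and adjusted p = 0.884 with an estimated correlation). Of the ribosomal protein genes 0 of 78 passed (median −0.29, adjusted p = 3.36e-05, and adjusted p = 0.884 with an estimated correlation). The spread here is that of the vehicle pairs. The count was 100 by limma-trend, 24 by DESeq2, 0 without a term for round, 0 in an additive design with 1 UV-A effect, 305 without a low-count filter and 344 with the GC and length offset. In the additive design, whose single UV-A effect is shared by vehicle and both compounds, it was 0 without either vehicle library of round 1 and 8 without either vehicle library of round 2, the same 8 as for vehicle.

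**Figure D2:**
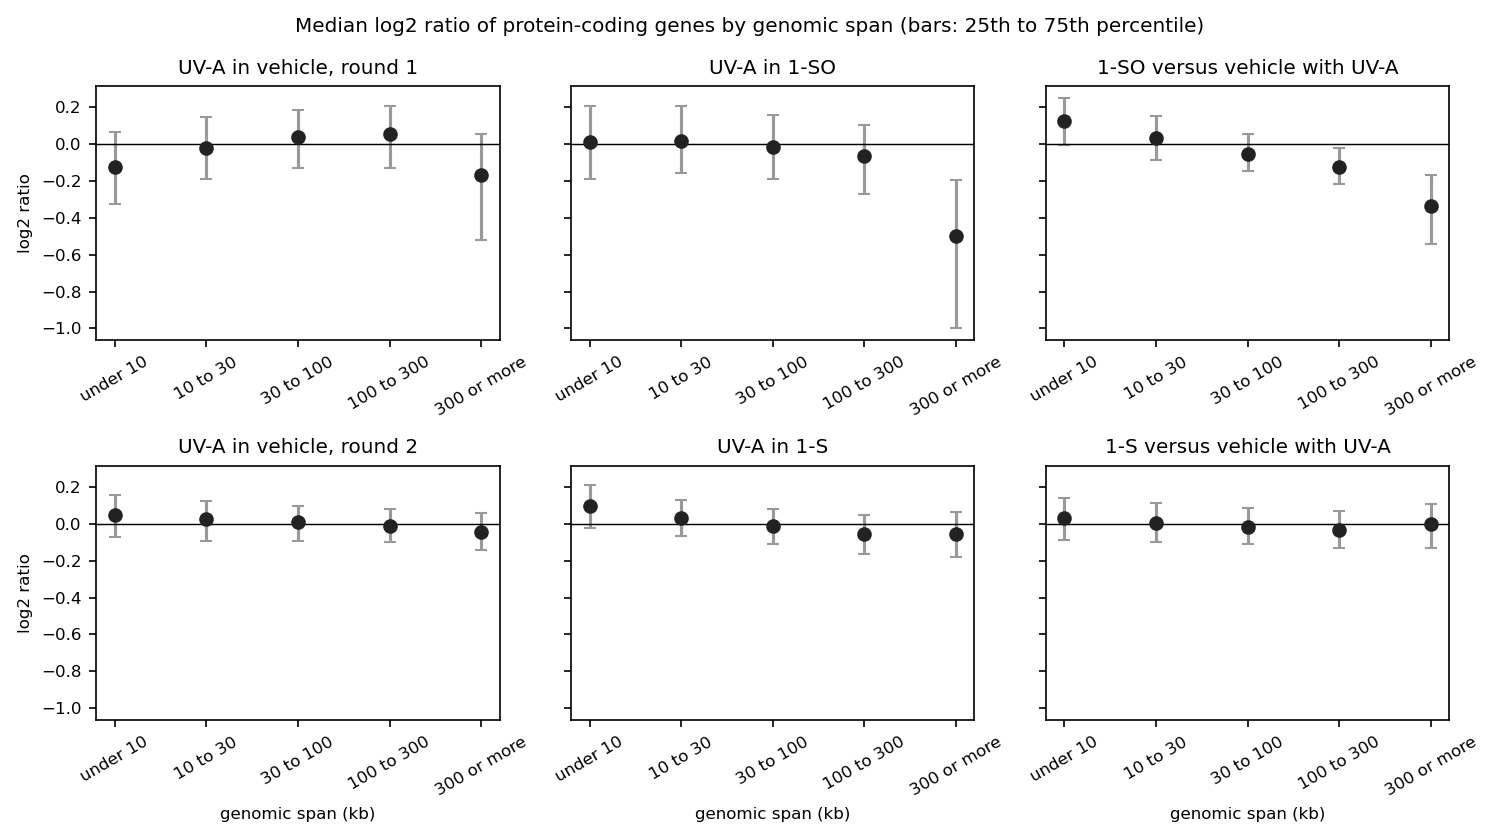
Median log2 ratio of protein-coding genes, with the 25th to 75th percentile, by genomic span in kb, for 6 pairs of libraries. For genes spanning 300 kb or more (361 genes) the median was −0.50 for UV-A in 1-SO, −0.165 for UV-A in vehicle of round 1 and −0.0418 for UV-A in vehicle of round 2. Genes under 10 kb (1758 genes) had medians of 0.012, −0.123 and 0.0471 in the same pairs.

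Whether 1-SO itself changed expression was asked without and with UV-A, against vehicle. Without UV-A the shielded 1-SO library lay close to its vehicle: the ratio within the round had a standard deviation of 0.097 over the 8491 genes with a mean log2 CPM of at least 4, against 0.0669 from counting alone, and 0 of these genes differed over 2-fold. Among protein-coding genes with a mean log2 CPM of at least 2 the largest fitted values were PSMG2, a proteasome assembly gene (1.15, ratio 1.97), FDPS, of isoprenoid synthesis (0.79, ratio within the round 0.94), EMG1 (0.77, ratio 0.80) and C2orf76 (0.72, ratio 0.58). On the other side stood CYP1A1 (−0.82 ± 0.406, ratio −0.17), MMP1 (−0.77, ratio −0.03), CTAGE5 (−0.76, ratio −0.52) and ZNF70 (−0.73, ratio −0.47). FOS (−0.17, ratio 0.07), EGR1 (−0.24, ratio 0.02) and HMOX1 (−0.04, ratio −0.04) did not pass. 0 genes passed with edgeR, limma-trend and DESeq2, and 49 had an unadjusted p under 0.05. Ribosomal protein genes had a fitted median of 0.119 (adjusted p = 0.00301, and adjusted p = 0.989 with an estimated correlation) but −0.0192 within the round. Respiratory chain subunits had 0.133 (adjusted p = 0.00301, and adjusted p = 0.989 with an estimated correlation) and 0.025 within the round. Replication genes had 0.144 (adjusted p = 0.0353, and adjusted p = 0.989 with an estimated correlation) and −0.0385 within the round, and turned to lower in the additive design (adjusted p = 0.42). Of these 3 lists 0 members passed, also adjusted over the list alone.

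With UV-A, 1 gene differed between 1-SO and vehicle. TBC1D5, a regulator of Rab GTPases with a span of 1287.7 kb (ENSG00000131374, chromosome 3, 17157162 to 18444817), was lower by −1.48 ± 0.24 (adjusted p = 0.0361), and the ratio within round 1 was −1.21. NEGR1 (−2.15, adjusted p = 0.0732, ratio −1.48), PARD3B (−2.005, adjusted p = 0.0883, ratio −1.46), FHIT (−2.16, ratio −0.93) and MALAT1 (−0.92, ratio −1.30) did not pass. MMP1 (1.53 ± 0.356, adjusted p = 0.119, ratio 1.06), ARC (1.36, adjusted p = 0.0883, ratio 1.08), PDK4, a kinase of pyruvate dehydrogenase (1.26, ratio 0.86), and EIF3L (1.09, ratio 0.91) were higher without passing, and CYP1A1 was at 0.77 (ratio 0.38). 490 genes had an unadjusted p under 0.05. The call of TBC1D5 was lost by limma-trend (adjusted p = 0.227), DESeq2 (adjusted p = 0.401) and without a term for round (adjusted p = 0.983). In the additive design TBC1D5 was at −0.34 (adjusted p = 1). That design has 1 effect of 1-SO over shielded and irradiated cells, where the ratios were 0.09 and −1.21, so it cannot test this call. It also gave 0 genes without each of the 4 vehicle libraries. In the planned design without the irradiated vehicle library of round 1 the fitted value of TBC1D5 was −2.14. The UV-A response of vehicle then comes from round 2 alone. That value thus also holds the UV-A response of round 1 and does not test the call. The count was 11 with RLE scaling, 34 without a low-count filter, 8 with a filter per round and 31 with the GC and length offset.

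By list, the contrast of 1-SO with vehicle under UV-A gave lower replication genes (median −0.31, ratio within the round −0.0867, adjusted p = 0.00168, and adjusted p = 0.8 with an estimated correlation). YAP and TGF-beta targets had a median of −0.24 (within the round −0.19, adjusted p = 0.00398, and adjusted p = 0.8 with an estimated correlation). Mitotic genes had −0.18 (within the round −0.22, adjusted p = 0.00798, and adjusted p = 0.8 with an estimated correlation). NRF2 targets had 0.25 (within the round 0.14, adjusted p = 0.00798, and adjusted p = 0.8 with an estimated correlation), respiratory chain subunits 0.125 (within the round 0.23, adjusted p = 0.0122, and adjusted p = 0.8 with an estimated correlation) and fatty acid synthesis genes −0.23 (within the round −0.165, adjusted p = 0.0416, and adjusted p = 0.8 with an estimated correlation). In these 6 lists 0 members passed, also adjusted over the list alone. The additive design, with 1 effect of 1-SO over both irradiation states, gave 2 lists. Long genes were lower here: in genes spanning 300 kb or more the median ratio of 1-SO to vehicle was −0.334, with 93.6% of 361 genes below 0. The trend ran over all spans, with medians of 0.128 under 10 kb, 0.0311 at 10 to 30 kb, −0.0523 at 30 to 100 kb and −0.122 at 100 to 300 kb. Short genes were thus higher. After the GC and length offset the median of the long genes was −0.226. Without that offset it was −0.334 as given. The median as counted was −0.27 among 174 such genes with a mean log2 CPM of at least 5, where short genes matched on expression gave between −0.0317 and 0.0272.

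1-SO with UV-A was also set against untreated vehicle. MMP1 rose by 2.75 ± 0.358 (adjusted p = 0.000254), ARC by 1.97, CYP1A1 by 1.87, CYP1B1 by 1.74, RRAD by 1.61, FOS by 1.53, SLC6A8, the creatine transporter, by 1.16 and SLC7A11 by 1.11. FHIT (−3.36), GPC6 (−3.26), NEGR1 (−3.06), PARD3B (−2.81), COL6A3 (−2.68), ANK2 (−2.58), RAD51B (−2.48) and NCAM2 (−2.34) fell, with MCM6 (−1.10) and PLAU (−1.14). Ratios within round 1 were 3.50 for MMP1, 2.32 for ARC, 2.49 for CYP1A1, 2.42 for CYP1B1, 1.80 for RRAD, 1.76 for FOS, 1.30 for SLC6A8 and 1.47 for SLC7A11. They were −3.57 for FHIT, −3.72 for GPC6, −3.44 for NEGR1, −3.10 for PARD3B, −2.94 for COL6A3, −2.93 for ANK2, −2.73 for RAD51B, −2.43 for NCAM2, −1.34 for MCM6 and −1.39 for PLAU. In all 113 genes passed (14 higher, 99 lower). Of 41 replication genes 2 fell (22 adjusted over the list alone, median −0.601, within the round −0.805, adjusted p = 1.55e-08, and adjusted p = 0.902 with an estimated correlation), and of 30 NRF2 targets 2 rose (7 alone, median 0.489, within the round 0.584, adjusted p = 3.61e-06, and adjusted p = 0.902 with an estimated correlation). The count was 73 by limma-trend, 17 by DESeq2, 0 without a term for round, 0 in the additive design, 226 without a low-count filter and 246 with the GC and length offset. In the additive design it was 0 without either vehicle library of round 1 and 2 without either of round 2. In that design, without the shielded vehicle library of round 1, the fitted values of FHIT (0.43) and GPC6 (1.11) turned positive. In the planned design without that library FHIT was at −1.28 and GPC6 at −0.20, with no test. Round 1 then has no untreated vehicle. These values join the ratio to irradiated vehicle of round 1 with the vehicle UV-A ratio of round 2. They therefore do not measure the change against untreated vehicle of round 1 and cannot test it. The authors' table for this pair held 50 passing genes, 13 higher and 37 lower, and their tables of 1-SO against vehicle at matched irradiation held 0.

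Whether 1-SO altered the response to UV-A was asked by the interaction. 2 genes passed, both lower: NEGR1 (−2.68 ± 0.466) and TBC1D5 (−1.79 ± 0.302), each at adjusted p = 0.0327. Within round 1 the difference of ratios was −1.60 for NEGR1 and −1.31 for TBC1D5. MMP1 (2.30, adjusted p = 0.16, within the round 1.08) and ARC (1.91, adjusted p = 0.137, within the round 1.28) did not pass, and 417 genes had an unadjusted p under 0.05. Replication genes had a median interaction of −0.437 (adjusted p = 2.98e-05, and adjusted p = 0.869 with an estimated correlation) and NRF2 targets 0.408 (adjusted p = 0.001, and adjusted p = 0.869 with an estimated correlation), with 0 members passing, also adjusted over the list alone. Within round 1 the medians for UV-A in 1-SO and in vehicle lay closer, at −0.74 and −0.635 for replication genes and 0.512 and 0.405 for NRF2 targets. The UV-A ratios in 1-SO and in vehicle of round 1, which share no library, had a correlation across genes of 0.406 over 15891 genes and 0.729 over the 8491 genes at a mean log2 CPM of at least 4. The count of 2 became 0 by limma-trend, DESeq2 and without a term for round, 6 with RLE scaling and with a filter per round, 32 without a low-count filter and 26 with the GC and length offset.

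For 1-S the same questions were asked in round 2. Without UV-A 0 genes passed with edgeR, limma-trend and DESeq2 (218 at an unadjusted p under 0.05), and the ratio within the round had a standard deviation of 0.118. The largest fitted values among protein-coding genes with a mean log2 CPM of at least 2 were PWP2 (2.18, ratio 2.28), NOP2, both of ribosome assembly (1.51, ratio 0.86), SNX15 (1.04, ratio 1.04) and TOP3B (0.97, ratio 1.16). Against them stood ZC3H11A (−3.85, SE 2390, ratio −0.92), PARL (−1.25, ratio −1.06), TXNDC5 (−1.02, ratio −0.84) and NUSAP1 (−0.94, ratio −0.97). With UV-A NOP2 (1.39, ratio 1.64), JTB (1.36, ratio 1.30), C21orf33 (1.33, ratio 1.27) and MFSD14A (1.22, ratio 0.95) stood against SLC25A32 (−5.44, SE 3030, ratio −2.40), NDUFS7 (−2.14, ratio −1.93), ARHGEF10 (−1.59, ratio −0.86) and MATR3 (−1.52, ratio −1.025), and none of these 8 passed. 0 genes passed with the 3 tools (342 at an unadjusted p under 0.05). Of the 15 genes named by fold in these comparisons, 14 had a level in vehicle of round 2 under an eighth of that in round 1, so their values rest on few counts. Ribosomal protein genes were lower without UV-A (median −0.24, within the round −0.105, adjusted p = 1.76e-07, and adjusted p = 0.918 with an estimated correlation) and higher with UV-A (0.18, within the round 0.0437, adjusted p = 0.000668, and adjusted p = 0.979 with an estimated correlation). With UV-A mitotic genes were lower (−0.26, within the round −0.21, adjusted p = 4.24e-05, and adjusted p = 0.979 with an estimated correlation) and NF-kB targets higher (0.20, within the round 0.19, adjusted p = 0.00237, and adjusted p = 0.979 with an estimated correlation), with CSF2 at 1.07 (ratio 0.94). In these lists 0 members passed, also adjusted over the list alone. The ribosomal direction with UV-A turned in the additive design (adjusted p = 0.577), where shielded and irradiated cells share 1 effect of 1-S. The mitotic direction turned without a term for round (adjusted p = 0.898).

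UV-A in cells exposed to 1-S called 0 genes with edgeR and DESeq2 and 1 with limma-trend, and 342 had an unadjusted p under 0.05. FOS (1.24 ± 0.301, adjusted p = 0.837), RHOB, a small GTPase gene of the immediate early list (1.08 ± 0.226, adjusted p = 0.443), and EGR1 (0.87) had the ratios 1.23, 1.08 and 0.87 within the round, where vehicle had 0.52, 0.14 and 0.25. ZC3H11A (3.98, ratio 0.94), TXNDC5 (1.53), PARL (1.38) and C12orf57 (1.26) stood against SLC25A32 (−5.25, ratio −1.73), ARHGEF10 (−1.84, ratio −1.36), TOP3B (−1.72, ratio −1.45) and DHPS (−1.68). All of them but TXNDC5 had a level in vehicle of round 2 under 1/8 of that in round 1. These levels lay between 0.0916 CPM (ZC3H11A) and 3.55 CPM (C12orf57), so the values rest on low counts. CYP1A1 (−0.01), MMP1 (0.01) and HMOX1 (−0.12) did not pass. Immediate early genes were above 0 for 32 of 37 members (0 passed, 7 adjusted over the list alone, adjusted p = 0.000136, and adjusted p = 0.949 with an estimated correlation). Against untreated vehicle, 1-S with UV-A gave 0 genes with the 3 tools (229 at an unadjusted p under 0.05), with FOS at 1.09 (ratio 0.89) and EGR1 at 0.81 (ratio 0.60). The interaction of 1-S with UV-A gave 0 with the 3 tools (491 at an unadjusted p under 0.05), with a median of 0.412 for ribosomal protein genes (0 passed, also adjusted over the list alone, adjusted p = 6.27e-10, and adjusted p = 0.927 with an estimated correlation). Within round 2 their medians for UV-A were 0.225 in 1-S and 0.0791 in vehicle. The 8 calls of the additive design without the shielded or without the irradiated vehicle library of round 2 are those given for vehicle and are not specific to 1-S. The authors' tables held 2 passing genes for 1-S with UV-A against shielded 1-S and 2 against untreated vehicle, JCHAIN and IGLC2 in both, and 0 against irradiated vehicle.

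**Figure D3:**
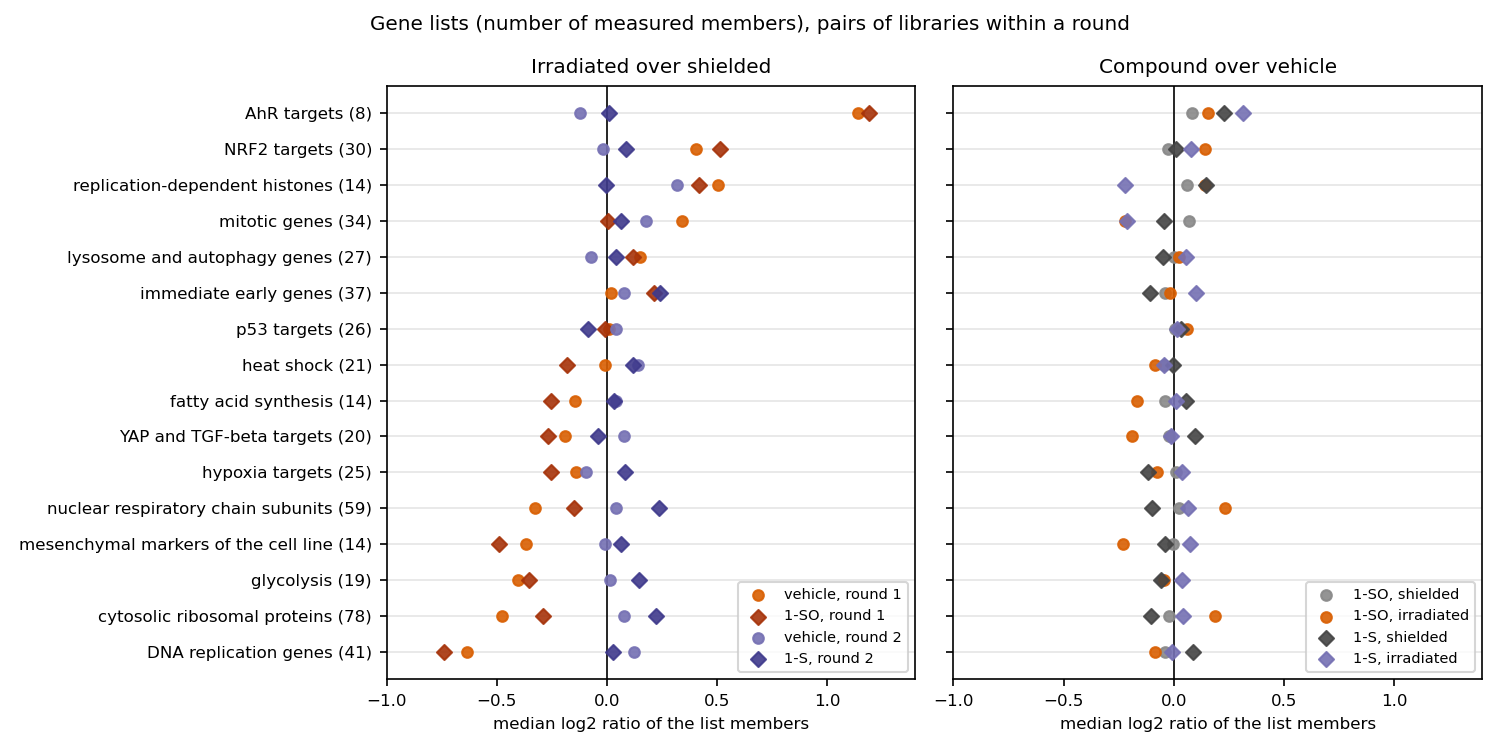
Median log2 ratio of 16 gene lists, with 1 point per pair of libraries, for irradiated over shielded pairs and for compound over vehicle pairs within a round. DNA replication genes lay at −0.635 with UV-A in vehicle of round 1 and −0.74 in 1-SO, and at 0.122 and 0.0264 in vehicle and 1-S of round 2.

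The S-oxide and the sulfide were compared at the same dose, 10 µM, and the same 24 h, as a contrast of 1 fit to both rounds, which is not the difference of the ratios to each round's own vehicle. Without UV-A the 2 compounds gave 0 differing genes with the 3 tools (213 at an unadjusted p under 0.05), and with UV-A also 0 (541 at an unadjusted p under 0.05, lowest adjusted p 0.0638). The 95% interval of the difference (1-SO minus 1-S) without UV-A was −0.90 to 0.51 for HMOX1, −0.77 to 0.40 for EGR1 and −0.80 to 0.77 for FOS, and −2.54 to −0.43 for CYP1A1. The ratios to vehicle within the round, 1-SO then 1-S, were −0.04 and 0.16 for HMOX1, 0.02 and −0.27 for EGR1, 0.07 and −0.34 for FOS, and −0.17 and 0.21 for CYP1A1, a smaller difference than the interval of CYP1A1 holds. With UV-A it was −3.38 to −1.47 for NEGR1 (−2.42 ± 0.466, adjusted p = 0.0836) and 1.16 to 3.14 for MMP1 (2.15). The ratios were −1.48 and −0.13 for NEGR1 and 1.06 and 0.18 for MMP1, also differences smaller than these intervals hold. Averaged over irradiation, in the design chosen after the data were seen, it was −0.46 to 0.50 for CYP1A1, −0.29 to 0.26 for CYP1B1, −0.29 to 0.30 for EGR1 and 0.06 to 0.87 for MMP1, and 0 genes passed (468 at an unadjusted p under 0.05). Replication genes differed with UV-A by a median of −0.529 (0 passed, also adjusted over the list alone, adjusted p = 3.82e-05, and adjusted p = 0.98 with an estimated correlation), while their medians within the rounds were −0.0867 and −0.00717. AhR targets differed without UV-A by −1.05 (0 passed, 3 adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.99 with an estimated correlation), while their medians within the rounds were 0.0845 and 0.229. The interval lay within a 2-fold difference either way for 56.9% of genes without UV-A, 54.1% with UV-A and 69.3% averaged. Across genes the 2 compounds' ratios to vehicle had a correlation of −0.00995 without and 0.0523 with UV-A. With UV-A the count became 6 with RLE scaling, 5 with a filter per round, 42 without a low-count filter and 39 with the GC and length offset.

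The UV-A response in 1-SO differed from that in 1-S for 26 genes, 5 more positive and 21 more negative in 1-SO. They include MMP1 (3.52 ± 0.56), CYP1A1 (2.70 ± 0.578), ARC (2.59 ± 0.461), CYP1B1 (2.46 ± 0.506) and SLC7A11 (1.74 ± 0.37), and FHIT (−3.94 ± 0.911), NEGR1 (−3.38 ± 0.519), PARD3B (−3.02 ± 0.516), COL6A3 (−2.81 ± 0.504) and ANK2 (−2.73 ± 0.495). 1-SO was run in round 1 and 1-S in round 2, and the vehicle pairs alone differed between these rounds by 2.58 for MMP1, 2.02 for CYP1A1, 1.38 for ARC, 2.25 for CYP1B1, −2.42 for FHIT and −1.98 for NEGR1. After each round's own vehicle ratio was taken off, 0.93 was left for MMP1, 0.64 for CYP1A1, 1.20 for ARC, 0.21 for CYP1B1, −1.28 for FHIT and −1.37 for NEGR1, with no test since each is a difference of single libraries. Replication genes had a median of −0.815 (0 passed, 22 adjusted over the list alone, adjusted p = 6.59e-08, and adjusted p = 0.819 with an estimated correlation), and their medians were −0.74 and 0.0264 for UV-A in 1-SO and 1-S and −0.635 and 0.122 in the vehicle of these rounds. The 26 genes therefore do not separate compound from round. The count was 0 by limma-trend, by DESeq2 and without a term for round, 95 without a low-count filter and 116 with the GC and length offset.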

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

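The tests of explanations in this part were chosen after results were seen, and for the overlap of gene models the prediction was written after the low counts were noticed and before any overlap was computed.

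The first pattern is the UV-A response of round 1 that was for the most part missing in round 2, marked because the difference between rounds passed for 1594 genes with the largest values at MMP1 (3.06), CYP1A1 (2.38), CYP1B1 (2.36), GPC6 (−3.56), FHIT (−3.16) and PRKG1 (−2.72). Part of it may be shared, as FOS and EGR1 rose in both rounds with edgeR. In round 2 these calls were lost with limma-trend, DESeq2 and the GC and length offset. Their ratios there were 0.52 and 0.25 in vehicle, and 1.23 and 0.87 in 1-S. The vehicle ratio of HMOX1 was 0.38 in round 1 and 0.39 in round 2, but its ratio in 1-S was −0.12. Lower depth in round 2 is argued against, since its lowest library count in genes listed in both rounds was 1.36 times that of round 1. A bias from GC content or transcript length is argued against by 1629 genes with the offset. Leaving out either irradiated library of round 1 cannot decide whether 1 of them was aberrant, since the spread then comes from the pairs of round 2 alone. The UV-A ratios in 1-SO and in vehicle of round 1, which share no library, had a correlation of 0.406 over 15891 genes. At a mean log2 CPM of at least 4 it was 0.729, so both irradiated libraries shared much of the response. Cell passage goes with the round (1 round per passage), and a difference in plate, lamp exposure or library batch could not be told apart from it although the labels give the same lamp settings, so these and a biological difference in sensitivity stay open hypotheses.

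The second pattern is the lower level of long genes after UV-A in round 1, lower again with 1-SO. It was marked because NEGR1 (−2.68) and TBC1D5 (−1.79) were the 2 genes passing the interaction of 1-SO with UV-A. Within round 1 the difference of ratios was smaller, at −1.60 and −1.31. The count was 0 with limma-trend and with DESeq2. In vehicle of round 1 genes under 10 kb were lower too (median −0.123, 67.2% below 0, against −0.165 and 68.4% at 300 kb or more). Genes of 30 to 100 kb (0.0371) and of 100 to 300 kb (0.0545) were higher. By span alone the fall in vehicle was thus not particular to long genes. Short genes matched on expression, transcript GC content and transcript length did not share it over all 361 long genes, as given below. A GC or length bias is argued against by a median of −0.422 after the offset for genes spanning 300 kb or more (UV-A in 1-SO). Counting noise at low expression is argued against in 1-SO by −0.321 among genes with a mean log2 CPM of at least 5. In vehicle of round 1 that median was −0.0509, inside the range of short genes matched on expression alone (−0.0696 to 0.0147). Over all 361 long genes it was −0.165, against 0.059 to 0.114 in short genes matched on expression, transcript GC content and transcript length. After the offset the median of these long genes was −0.198, against 0.0209 to 0.0793 in the matched short genes. These results differ, but the tests differ in the matching as well as in the genes used. Low expression therefore stays an open explanation there. In round 2, again at a mean log2 CPM of at least 5, the median was −0.0242 in vehicle (matched 0.0087 to 0.0546). In 1-S it was −0.0672 (matched −0.00166 to 0.047). That UV-A lowers long transcripts, more so with 1-SO, stays a hypothesis, with 1 shielded and 1 irradiated plate per round.

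The third pattern is the set of 26 genes in which the UV-A response in 1-SO differed from that in 1-S, marked by MMP1 (3.52), CYP1A1 (2.70), ARC (2.59), CYP1B1 (2.46), SLC7A11 (1.74), FHIT (−3.94), NEGR1 (−3.38), PARD3B (−3.02), COL6A3 (−2.81) and ANK2 (−2.73). The vehicle pairs, which hold no compound, differed between the same rounds by 2.58 for MMP1, 2.25 for CYP1B1 and −2.42 for FHIT. The count was 0 without a term for round, where the difference between rounds in vehicle enters the spread. That count therefore does not bear on compound against round. Compound and round stay inseparable, with 1 round per passage.

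Among genes with nearly no counts in vehicle of round 2, reads lost to overlapping gene models of the newer annotation are a candidate explanation: at least 50% of exonic bases were overlapped in 36.9% of 84 such genes and 0.142% of 9166 others, a ratio of 260 (Fisher exact p = 4.41e-56). For 15 of the 84, with 0% overlap, that explanation is argued against and the cause was not tested.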

How the results depend on the processing

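Of the settings below, the ones with a UV-A effect per round, the filter per round and the GC and length offset were chosen after results were seen. Most compound comparisons rest on 1 library per group, and the spread comes from the vehicle pairs, whose UV-A response differs between rounds. Across settings, called genes stayed the same in 849 of 1297 values, lost the call in 364, moved in 82 and reversed in 2. In settings with a test, the same means the same sign and call, and size was not checked. In values without a test it means within 1 SE. Genes given as values stayed the same in 4766 of 5622, and list results in 380 of 722, with 334 weaker and 8 reversed. Beyond what is said below of the additive design and the replicate block, the cause of these changes was not tested.

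With DESeq2 the count was 0 for 1-SO with UV-A, 24 for UV-A in 1-SO, 17 for 1-SO with UV-A versus untreated vehicle, 0 for the interaction of 1-SO with UV-A, 0 for the UV-A response in 1-SO against 1-S, 1329 for UV-A in round 1, 3 in round 2 and 801 for the difference between rounds. With limma-trend it was 0 for 1-SO with UV-A, 100 for UV-A in 1-SO, 1 for UV-A in 1-S, 73 for 1-SO with UV-A versus untreated vehicle, 0 for the interaction of 1-SO with UV-A, 0 for the UV-A response in 1-SO against 1-S and 3 for UV-A in round 2. RLE scaling gave 1 for UV-A in vehicle, 11 for 1-SO with UV-A, 6 for the interaction of 1-SO with UV-A and 6 for 1-SO against 1-S with UV-A, and it kept 109 of 109 called genes.

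Without a low-count filter the count was 22 for UV-A in vehicle, 34 for 1-SO with UV-A, 305 for UV-A in 1-SO, 1 for UV-A in 1-S, 226 for 1-SO with UV-A versus untreated vehicle, 32 for the interaction of 1-SO with UV-A and 4 for that of 1-S. It was 1 for 1-SO against 1-S without and 42 with UV-A, 95 for the UV-A response in 1-SO against 1-S, 51 for UV-A in round 2 and 3 for 1-SO averaged over irradiation. A filter per round gave 2 for UV-A in vehicle, 8 for 1-SO with UV-A, 6 for the interaction of 1-SO with UV-A and 5 for 1-SO against 1-S with UV-A. The GC and length offset gave 25 for UV-A in vehicle, 31 for 1-SO with UV-A, 344 for UV-A in 1-SO, 2 for UV-A in 1-S, 246 for 1-SO with UV-A versus untreated vehicle, 26 for the interaction of 1-SO with UV-A and 1 for that of 1-S. It gave 39 for 1-SO against 1-S with UV-A, 116 for the UV-A response in 1-SO against 1-S and 2 for UV-A in round 2.

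Round was the replicate block. Without it the difference between rounds enters the spread of the vehicle libraries. For shielded vehicle that difference had a standard deviation of 0.498 at a mean log2 CPM of at least 4. Calls lost in this setting therefore do not bear on compound against round. With no replicate block the count was 0 for 1-SO with UV-A, UV-A in 1-SO (0), 1-SO with UV-A versus untreated vehicle (0), the interaction of 1-SO with UV-A (0) and the UV-A response in 1-SO against 1-S (0), and 55 of 55 called genes lost their call. The number of gene lists passing camera became 6 for 1-S without UV-A, 10 for 1-S with UV-A, 2 for 1-S with UV-A versus untreated vehicle and 4 for the interaction of 1-S with UV-A. Mitotic genes turned direction in 1-S with UV-A (adjusted p = 0.898). It changed no other count by more than the 1.5-fold used here.

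The additive design has 1 UV-A effect and 1 effect per compound, so it cannot test effects that depend on both. In that design the count was 0 for 1-SO with UV-A, 0 for UV-A in 1-SO and 0 for 1-SO with UV-A versus untreated vehicle. Lists passing became 2 for 1-SO with UV-A, 3 for 1-S with UV-A, 10 for UV-A in 1-S, 8 for 1-S with UV-A versus untreated vehicle, and 2 for 1-SO against 1-S without and 2 with UV-A. Directions turned for replication genes in 1-SO without UV-A (adjusted p = 0.42) and for respiratory chain subunits (0.639) and ribosomal protein genes (0.577) in 1-S with UV-A. They turned for respiratory chain subunits (0.223) and ribosomal protein genes (0.00485) in UV-A in 1-S, and for replication genes (0.379) and glycolysis (0.868) in 1-SO against 1-S without UV-A. Interactions have no additive or leave-one-out test.

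Leaving out each vehicle library (additive design) gave 0 to 8 for UV-A in vehicle, 0 to 8 for UV-A in 1-SO, 0 to 8 for UV-A in 1-S (the same 8 calls, since this design has 1 UV-A effect), 0 to 2 for 1-SO with UV-A versus untreated vehicle and 0 to 0 for 1-SO with UV-A. Leaving out an irradiated library of round 1 gave 1036 to 1491 for UV-A in round 1, 43 to 51 in round 2, 1103 to 1165 for the difference between rounds and 2 to 2 for 1-S averaged over irradiation. In 1-SO with UV-A versus untreated vehicle FHIT ranged from −1.78 to 0.43 and GPC6 from −2.17 to 1.11 in the additive design, reversed without the shielded vehicle library of round 1.

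With an estimated correlation 0 lists passed in each of the 20 comparisons, as 1 or 2 residual degrees of freedom leave that test almost no power. With fry 0 passed in each, except 3 for UV-A in round 1 and 4 for the difference between rounds. Correlations at a mean log2 CPM of at least 4 were −0.185 for UV-A in vehicle of round 1 and round 2, −0.116 for 1-SO without and with UV-A, −0.2 for 1-S without and with UV-A, 0.164 for 1-SO and 1-S with UV-A and 0.729 for UV-A in 1-SO and in vehicle of round 1, the last 0.572 with FPKM.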

Other observations

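The genes and libraries of this part were chosen after their values were seen.

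Immunoglobulin transcripts, which plasma cells make and breast cancer cells are not known for, appeared in irradiated libraries of round 2. JCHAIN, the joining chain, and IGLC2, a light chain constant region, were at 0 CPM in the 4 libraries of round 1. JCHAIN was at 0.528 in irradiated vehicle and 1.36 in irradiated 1-S, and 0 in the 2 shielded libraries of round 2. IGLC2 was at 0.72 and 2.20, and at 0 in shielded vehicle and 0.047 in shielded 1-S. Both are among the 12 genes called with UV-A in round 2, and the source of these reads was not tested.

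MALAT1, a nuclear noncoding RNA, had a UV-A ratio of 1.64 in vehicle of round 1 and 0.08 in 1-SO, and −0.12 and −0.59 in vehicle and 1-S of round 2. NEAT1, a nuclear paraspeckle RNA, had 0.46 and 0.30 in round 1 and −0.54 and −0.69 in round 2. IFIT2, an interferon-induced gene, was at 0.46 ± 0.0964 for 1-S averaged over irradiation (edgeR quasi-likelihood adjusted p = 0.618). In that average AhR targets were above 0 for 8 of 8 members (0 passed, 2 adjusted over the list alone, median 0.272, adjusted p = 6.44e-05, and adjusted p = 0.921 with an estimated correlation).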
